A study of Mus musculus with 23 samples.

How the data were processed

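MicroRNA was profiled in 23 samples of sorted bone marrow cells, 4 cell types from 2 mouse strains, on 1-colour (Cy3) Agilent mouse miRNA arrays with probes for 567 mouse and 10 viral miRNAs and 100 ng of RNA per array. Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 9.5.3.1, and the scanner files hold signal as linear intensity, background-subtracted and not normalized between arrays. The deposited value table holds log2 values that the authors scaled and centred, with column medians from -3.22 to -1.67. The processed signal table of the authors holds intensity, the scanner software's total signal per probe. The genome build of the probe positions is not given in the sources used here, so no position is given.

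Scanner files exist for 22 of the 23 samples, and D2 Gr1 replicate 2 has none, so it enters the fits on the authors' tables alone. Of the 23 columns of the value table that were compared, 12 equal the scanner file of their own sample (median absolute deviation up to 0.01 log2), 9 that of another replicate of the same group, 0 that of another group, and 2 (B6 Prog replicate 2 and D2 Gr1 replicate 1) none. The B6 Prog replicate 2 column correlates with its scanner file at r = 0.252 across miRNAs. All 22 columns of that processed source that have a scanner file equal its totals, 2603 of the cells are blank, and 1 column, named as B6 Prog replicate 3, matches no sample and was not used in any step. The processed column of D2 Gr1 replicate 2 correlates at 0.982 and 0.996 across miRNAs with D2 Gr1 replicates 1 and 3. The series text says that a B6 LS−K+ replicate was removed by the authors after a principal component analysis, without saying which.

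The analysis used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for the plot. Control spots (953 of 12493) and outlier spots were left out. Log2 processed signal was scaled by subtracting each array's 75th percentile over probes well above background on all arrays, where a probe counts when at least 0.5 of its spots are. Values below a floor, the median over arrays of the 1st percentile among probes well above background (log2 -6.08, or -4.38 without B6 Prog replicate 2), were set to the floor. Spots of a probe were averaged, and each miRNA took its brightest probe. Values at the floor have no spread. The signal over background limits what can be seen, and the number of arrays limits the precision: across 20 replicate pairs r was 0.390 to 0.993. The lowest value was the B6 Prog pair, which includes replicate 2, and the next lowest was 0.960.

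One limma fit covered the 8 groups without a block, with 14 residual degrees of freedom and a prior of 5.30 (13 and 2.90 without B6 Prog replicate 2). Cell type contrasts are means of the B6 and D2 differences. Tests are two-sided, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05, and the interaction is the moderated F-test of limma. The labels call the samples biological replicates and do not say more about animals, so p-values measure the spread between these samples. Replicate numbers showed no pairing of arrays on average: without B6 Prog, residuals of arrays with the same number correlated at a mean r of -0.0174 (57 pairs, from -0.507 to 0.515) and with different numbers at 0.00758 (114 pairs). As 9 columns of the value table equal the scanner file of another replicate, the numbers are in doubt and pairing is not excluded. The arrays lie on 3 slides: A holds 6 LSK and 2 Gr1 arrays, B 4 Prog, 1 Gr1 and 3 Ter119, and C 1 Prog, 2 Gr1 and 3 Ter119.

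The named miRNAs follow a rule fixed before the data were examined. For cell types it takes the 8 called miRNAs with the largest change in each direction and the tested members of the stem and progenitor, erythroid, granulocytic and lymphoid lists. For strains it takes up to 8 called miRNAs in each direction and the miR-99b cluster, for the interaction the 8 with the smallest p, and from the other lists up to 4 members. Further miRNAs named from the fit without B6 Prog replicate 2 were chosen after their values were seen. miRNA lists were written from textbook knowledge before the data were examined: stem and progenitor, erythroid, granulocytic, lymphoid, non-haematopoietic, the miR-99b cluster, the miR-99 and miR-125 families, the miR-17 family clusters, the let-7 family, miR-23, miR-27 and miR-24, the miR-29 family, miR-15 and miR-16, the X-linked miR-322 cluster, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 intronic cluster. The 11 lists with at least 3 tested members were tested by camera with a preset correlation of 0.01 in 9 comparisons, 99 tests adjusted together, which gave 8 calls with all arrays, of which 0 hold with an estimated correlation, and 18 without B6 Prog replicate 2, of which 4 hold.

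Alternatives fixed before the data were examined changed the scaling, background, floor, miRNA summary, filter, threshold, fit, block and value source, and left out each array in turn. The fit as designed holds all 22 arrays. Leaving out B6 Prog replicate 2 in results on LSK, Gr1 and Ter119, and joining this with other choices, was chosen after seeing the data. Both sets of values had been seen when the designed fit was set first. The procedure was tested on simulated data with 99 miRNAs, of which 20 changed in each of 100 draws. In the simulated Prog and LSK comparison 15.7% of changes of 0.5 log2, 68.7% of 1 and 98.7% of 2 were called, with a false share of 5.13%. The shares were 5.29%, 45.6% and 95% for strain in LSK (false share 5.50%) and 3.57%, 27.3% and 88% for strain in Prog (4%). For the stem and progenitor list in LSK the list test called 3% of draws with no change and 98% with a change of 0.5 log2. The simulated noise was independent between miRNAs, with no floor and no scaling error. These shares therefore do not measure how correlation between miRNAs affects the list calls in the real arrays.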

Results

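MicroRNA levels were measured in 4 cell populations sorted from the bone marrow of mice of the inbred strains B6 and D2. LSK cells are the Sca-1 and c-Kit positive fraction that holds the multilineage stem and progenitor cells. LS−K+ cells (Prog below) are committed progenitors, Gr-1+ cells (Gr1) are myeloid, and TER-119+ cells (Ter119) are erythroid. Scanner files of 22 arrays were used: 3 each for B6 LSK, D2 LSK, D2 Prog, B6 Gr1, B6 Ter119 and D2 Ter119, and 2 each for B6 Prog and D2 Gr1. Of the 567 mouse miRNAs on the array, 99 were well above background on every array of at least 1 group and were tested. Values are log2 of scaled signal, changes are given ± SE of the limma fit, and the number of arrays limits the precision. Each SE pools a miRNA's spread over the 8 groups, and groups at the floor add no spread. For a miRNA at the floor in Gr1 and Ter119, the SE and p-value in LSK and Prog can therefore be too small. This bears on the stem and progenitor list, where 8 of 12 tested members were not well above background on any Gr1 or Ter119 array.

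B6 Prog replicate 2 stood apart from all other arrays. Its negative control spots spread by 517 signal units, against 11.5 to 39.3 on the other arrays. On it 645 spots were well above background against 885 to 1883, and its highest Spearman correlation with any array was 0.188. With it, 6 probes were well above background on all arrays and set the scaling, and without it 62. Each comparison below is therefore given with all 22 arrays, as the design fixed before the data were examined has it. The value without that array stands beside it ("without"), and there B6 Prog has 1 array that is assumed to vary like the other groups.

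The first comparison asked how committed progenitors differ from the LSK fraction. The stem and progenitor list fell from LSK to Prog: 11 of 12 tested members were lower, 11 when adjusted over the list alone, with a median of -1.51 (12 of 12, 12 and -1.61 without), while miR-221 was higher in Prog with no scaling. miR-125b-5p, a regulator of stem cell number, changed by -2.07 ± 0.39 (-2.61 ± 0.09 without), miR-155 by -1.82 ± 0.30 (-2.09 ± 0.07 without), miR-10a by -1.80 ± 0.36 (-2.15 ± 0.12 without) and miR-196b, which lies in a Hox cluster, by -1.69 ± 0.39 (-2.25 ± 0.06 without) (5 Prog and 6 LSK arrays). miR-223, the main miRNA of granulocytes, rose by 1.73 ± 0.27 (2.09 ± 0.20 without), in 5 of 5 Prog arrays. let-7e was on no Prog array well above background and was at least 1.83-fold higher in LSK (2.6-fold without), where the bound sets the bright group's mean against the lowest signal well above background on the dim arrays. Of the 12 tested members of the miR-17 family clusters, which promote proliferation, 3 were higher and 2 lower, 0 and 0 adjusted over the list alone, with miR-18a at 0.76 ± 0.31 (1.64 ± 0.13 without). With that array left out, 9 were higher and 1 lower, adjusted over the list alone too. The let-7 family had 7 of 9 tested members lower (8 adjusted over the list alone), and all 3 tested members of the miR-29 family were lower (3 adjusted over the list alone), with miR-29b at -1.89 ± 0.36 (-0.98 ± 0.20 without). Among markers of maturing cells, miR-486, an erythroid miRNA on no LSK array well above background, was at least 1.36-fold higher in Prog (1.25-fold without), while miR-24 of the granulocytic list fell, at -2.05 ± 0.28 (-1.25 ± 0.12 without).

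In all, 50 of 99 miRNAs were called between Prog and LSK at an adjusted p under 0.05, 9 higher and 41 lower in Prog, and 65 (22 and 43) without B6 Prog replicate 2. Of these 45 were in both sets. The list test called the stem and progenitor list lower (adjusted p = 0.00325), and the adjusted p = 0.976 with an estimated correlation. With that array left out these were adjusted p = 2.50e-07 and adjusted p = 0.0202 with an estimated correlation. There the miR-17 family clusters were called higher (adjusted p = 3.55e-05, and adjusted p = 0.299 with an estimated correlation). LSK and Prog arrays share no slide, so slide can be separated only through Gr1: with slide as a block 0 miRNAs were called (52 without B6 Prog replicate 2), and no within-slide value exists. The split depended on the scaling: scaling on all probes gave 9 higher and 15 lower (21 and 11 without B6 Prog replicate 2), quantile normalization 14 and 33 (27 and 29), and no scaling 22 and 10 (34 and 10). The authors' own values gave 40 and 16, but they differ in more than the scaling. Their B6 Prog replicate 2 column equals no scanner file.

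**Figure D1:**
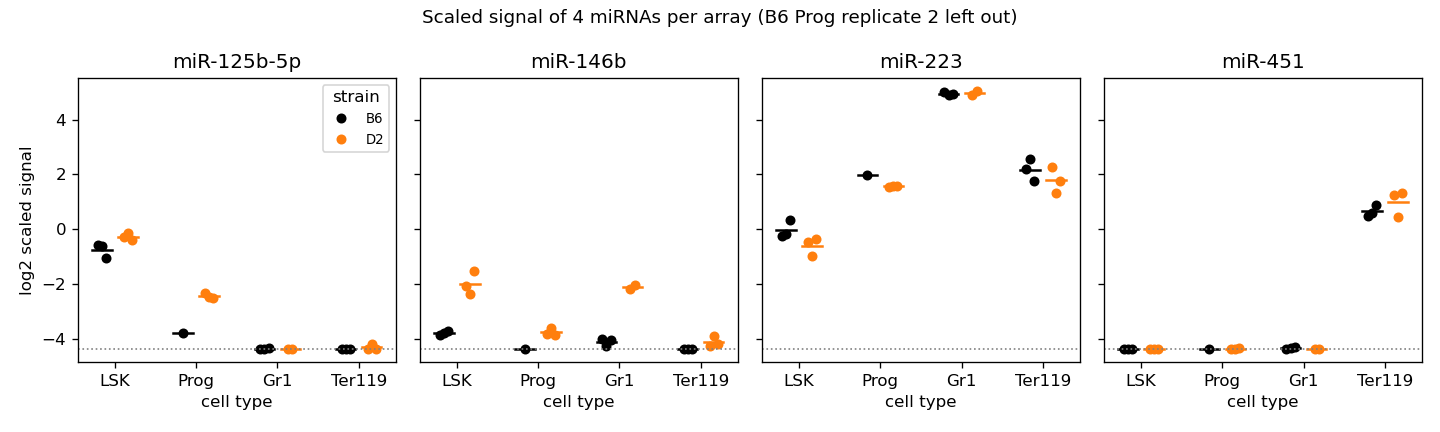
Log2 scaled signal (vertical axis) of miR-125b-5p, miR-146b, miR-223 and miR-451 in the 4 cell types (horizontal axis) for B6 (black) and D2 (orange), 1 point per array, with a short line at each group's mean and a dotted line at the floor of -4.38, without B6 Prog replicate 2. miR-125b-5p is highest in LSK, miR-223 in Gr1 and miR-451 in Ter119, and miR-146b lies higher in D2 than in B6 in LSK and Gr1 by 1.81 and 1.99.

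The second comparison set myeloid Gr1 cells against Prog, where the median of all tested miRNAs was -0.87 (0.01 without). miR-223 rose further, by 1.89 ± 0.28 (3.19 ± 0.21 without), in 5 of 5 Gr1 arrays. miR-139-5p and miR-22 were on no Prog array well above background and were at least 1.9-fold and 1.18-fold higher in Gr1 (8.46-fold and 5.26-fold without). The miR-17 family clusters fell, with 11 of 12 tested members lower, 11 adjusted over the list alone (10 and 10 without). Examples are miR-20b at -2.84 ± 0.23 (-1.62 ± 0.10 without), miR-19b at -2.74 ± 0.29 (-1.75 ± 0.21 without) and miR-92a at -2.65 ± 0.23 (-1.30 ± 0.15 without). Of the stem and progenitor list, 7 of 12 were lower, 7 adjusted over the list alone (2 higher and 8 lower, 2 and 8 without). miR-125b-5p was on no Gr1 array well above background and was at least 4.18-fold lower (1.86-fold without). The let-7 family had 8 of 9 members lower, 8 adjusted over the list alone (6 and 6 without), with let-7b at -2.76 ± 0.29 (-1.06 ± 0.16 without). However, let-7c, let-7d and let-7i were higher with scaling on all probes and with quantile normalization. Some values changed sign with the array set and passed the test without B6 Prog replicate 2: miR-27a, which passed in both, was -0.95 ± 0.38 (1.04 ± 0.18 without) and miR-142-3p -0.51 ± 0.29 (1.11 ± 0.25 without). miR-150, abundant in lymphocytes and on no Prog array well above background, was called without that array alone, where it was at least 1.47-fold higher in Gr1. miR-23a was 0.50 ± 0.24 (1.71 ± 0.11 without) and passed the test without B6 Prog replicate 2 alone.

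Between Gr1 and Prog 58 miRNAs were called, 5 higher and 53 lower in Gr1, and 70 (34 and 36) without B6 Prog replicate 2. Of these 39 were in both sets. The list test called the miR-17 family clusters (adjusted p = 0.011, and adjusted p = 0.976 with an estimated correlation) lower. It also called the let-7 family (adjusted p = 0.0471, and adjusted p = 0.976 with an estimated correlation) lower. With that array left out it called the miR-17 family clusters lower (adjusted p = 5.42e-04, and adjusted p = 0.406 with an estimated correlation). It called miR-15 and miR-16 higher, 3 of 3 (3 adjusted over the list alone, adjusted p = 0.0294, and adjusted p = 0.13 with an estimated correlation), but not the let-7 family. With slide as a block 37 were called (65 without that array), and within slides B and C 58 and 55 of the 58 calls had the same sign. The higher and lower calls were 22 and 20 with scaling on all probes, 35 and 23 with quantile normalization, 11 and 36 with no scaling, and 23 and 50 in the authors' own log2 values.

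The third comparison set erythroid Ter119 cells against Prog. All 4 tested members of the erythroid list rose (4 adjusted over the list alone). miR-451, the erythroid miRNA of the miR-144 cluster, was on no Prog array well above background and was at least 20.6-fold higher in Ter119 (33.3-fold without). miR-486 rose by 3.32 ± 0.22 (3.53 ± 0.13 without), miR-15a by 1.83 ± 0.33 (1.04 ± 0.11 without) and miR-16 by 1.95 ± 0.47 (0.74 ± 0.07 without), in 6 of 6 Ter119 arrays each. miR-494, miR-709, miR-714, miR-689 and miR-671-5p rose too, for example miR-494 by 3.24 ± 0.42 (3.79 ± 0.41 without) and miR-709 by 2.54 ± 0.32 (2.59 ± 0.30 without). Of the stem and progenitor list 8 of 12 were lower, 9 adjusted over the list alone (9 and 9 without). miR-196b and miR-221 were on no Ter119 array well above background and were at least 2.85-fold and 2.32-fold lower (1.68-fold and 1.92-fold without). The miR-17 family clusters had 2 members higher and 8 lower, 3 and 8 adjusted over the list alone (0 and 9, 0 and 9 without). Of the lymphoid markers, miR-150 was at least 3.25-fold higher in Ter119 (5.25-fold without). miR-342-3p passed the test without B6 Prog replicate 2 alone, where it was at least 3.65-fold higher, and miR-181b was lower, at -1.75 ± 0.55 (-0.54 ± 0.11 without). miR-146a, on no Prog array well above background, was at least 1.51-fold higher (2.44-fold without).

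Between Ter119 and Prog 54 miRNAs were called, 23 higher and 31 lower in Ter119, and 72 (30 and 42) without B6 Prog replicate 2. Of these 50 were in both sets. The list test called the erythroid list higher (adjusted p = 0.00325, and adjusted p = 0.116 with an estimated correlation, and 0.00429 and 0.0552 without). It called the stem and progenitor list lower (adjusted p = 0.0136, and adjusted p = 0.976 with an estimated correlation, and 0.0183 and 0.347 without). Without that array it also called the miR-17 family clusters lower (adjusted p = 0.0294, and adjusted p = 0.704 with an estimated correlation). With slide as a block 44 were called (75 without), and within slides B and C 54 and 53 of the 54 calls had the same sign. The higher and lower calls were 27 and 20 with scaling on all probes, 30 and 24 with quantile normalization, and 22 and 60 in the authors' own log2 values.

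The mature lineages were also set against each other. miR-223 was higher in Gr1 by 1.51 ± 0.27 (2.98 ± 0.18 without), miR-10a by 0.996 ± 0.36 (2.42 ± 0.10 without) and miR-139-5p by 0.99 ± 0.31 (2.43 ± 0.13 without), each in 5 of 5 Gr1 arrays. miR-451 was lower in Gr1, where its mean lay at the floor, with 1 of 5 Gr1 and 6 of 6 Ter119 arrays well above background, and miR-486 was at least 19-fold lower (13.9-fold without). miR-494 and miR-709 were lower, at -5.48 ± 0.42 (-4.04 ± 0.36 without) and -3.50 ± 0.32 (-2.04 ± 0.26 without). Of the lymphoid list 3 of 5 were lower in Gr1, 3 adjusted over the list alone (2 and 2 without). Of the erythroid list 3 of 4 were lower, 3 adjusted over the list alone (2 higher and 2 lower, 2 and 2 without). miR-150 was at -2.58 ± 0.27 (-1.84 ± 0.12 without) and miR-342-3p was at -1.99 ± 0.51 (-0.98 ± 0.13 without). miR-142-3p, miR-21 and miR-15a were lower in Gr1 with all arrays and had the opposite sign without B6 Prog replicate 2, at -0.77 ± 0.28 (0.69 ± 0.21 without), -1.13 ± 0.40 (0.33 ± 0.18 without) and -0.86 ± 0.33 (0.61 ± 0.09 without), where miR-21 did not pass. Of miR-23, miR-27 and miR-24, 0 of 5 passed with all arrays, and 4 of 5 were higher in Gr1 without B6 Prog replicate 2 (4 adjusted over the list alone), with miR-24 at 1.57 ± 0.10.

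Between Gr1 and Ter119 56 miRNAs were called, 3 higher and 53 lower in Gr1, and 60 (30 and 30) without B6 Prog replicate 2. Of these 31 were in both sets. The list test called the stem and progenitor list higher (adjusted p = 0.00325, and adjusted p = 0.976 with an estimated correlation), although the median was -0.01, the mean 0.06 and 1 of 12 members passed (0 adjusted over the list alone). As 8 of the 12 were on no Gr1 or Ter119 array well above background, their change is set by the floor. The median of all tested miRNAs was -0.79, so this call does not show a rise of the list in Gr1. Without B6 Prog replicate 2 the list test called miR-23, miR-27 and miR-24 higher instead (adjusted p = 0.0224, and adjusted p = 0.421 with an estimated correlation). With slide as a block 45 were called (56 without), and within slides B and C 55 and 56 of the 56 calls had the same sign. The higher and lower calls were 14 and 17 with scaling on all probes, 20 and 17 with quantile normalization, 14 and 16 with no scaling, and 23 and 28 in the authors' own log2 values.

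The strains were compared within each cell type. In LSK, 5 miRNAs were higher in D2: miR-146b by 2.34 ± 0.36 (1.81 ± 0.16 without), let-7e by 1.43 ± 0.30 (0.90 ± 0.11 without), miR-222 by 1.20 ± 0.34 (0.67 ± 0.11 without), miR-99a by 1.16 ± 0.31 (0.64 ± 0.10 without) and miR-542-5p by 1.05 ± 0.30 (0.54 ± 0.07 without), each in 3 of 3 D2 arrays. The median of all tested miRNAs was 0.45 there (0 without), although the LSK arrays are the same in both fits. Part of each LSK change with all arrays is therefore common to most miRNAs and comes with the scaling. Of the stem and progenitor list 4 of 12 were higher, 6 adjusted over the list alone, with a median of 1.07 (8, 10 and 0.55 without). In the miR-99b cluster 1 of 3 tested members, let-7e, was higher, and miR-125a-5p was 1.11 ± 0.67 (0.61 ± 0.07 without) and passed without B6 Prog replicate 2 alone. Without that array 19 were called in LSK, 13 higher and 6 lower in D2, including all 5 (11 to 20 leaving out 1 further LSK array, 1 with scaling on all probes, 24 with quantile normalization and 0 with normexp). There miR-130a was 0.97 ± 0.09, and the miR-17 family clusters had 4 of 12 members lower (4 adjusted over the list alone, adjusted p = 0.00588, and adjusted p = 0.637 with an estimated correlation). The list test called the stem and progenitor list higher in D2 LSK (adjusted p = 0.00138, and adjusted p = 0.976 with an estimated correlation). The values without that array were adjusted p = 2.50e-07 and adjusted p = 0.0202 with an estimated correlation. All LSK arrays lie on 1 slide. With all arrays 1 was called in LSK with scaling on all probes, 3 with quantile normalization, 2 with slide as a block, and 0 by limma with normexp or with no floor, and 41 were called without D2 LSK replicate 2 (20 without B6 Prog replicate 2 too).

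In Prog, 13 miRNAs were called with all arrays, 8 higher and 5 lower in D2, with miR-16 at 2.37 ± 0.71 and miR-106b at 1.87 ± 0.55. 12 of the 13 were not called without B6 Prog replicate 2, where miR-16 was -0.11 ± 0.11. miR-34a was the 1 call in both sets and was lower in D2, at -1.30 ± 0.36 (-0.85 ± 0.22 without), but higher with scaling on all probes. Without that array 6 were called, 5 higher in D2: miR-125b-5p (1.35 ± 0.15), miR-196b (0.74 ± 0.10), miR-130a, miR-99a and miR-222, all of the stem and progenitor list, with 3 D2 arrays against 1 B6 array. On that B6 array miR-130a, miR-99a and miR-222 were not well above background, so they were at least 1.91-fold, 1.42-fold and 1.36-fold higher. The scanner software detected 82 miRNAs on it, against 89 to 106 on the 3 D2 Prog arrays. Its negative control spots spread by 30.1 signal units, against 12.9 to 39.3. Whether the quality of this 1 array contributes was not tested. The list test called the miR-17 family clusters higher in D2 with all arrays (3 of 12 members, 6 adjusted over the list alone, adjusted p = 0.00325, and adjusted p = 0.976 with an estimated correlation). Without that array it called the stem and progenitor list higher instead (5 of 12, 7 adjusted over the list alone, adjusted p = 9.06e-10, and adjusted p = 0.013 with an estimated correlation). With slide as a block 0 were called with all arrays and 6 without that array, and within slide B 13 of the 13 calls had the same sign. The higher and lower calls were 56 and 0 with scaling on all probes and 44 and 2 with quantile normalization, and 0 were called with no scaling or with normexp, with or without that array.

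In Gr1 and in Ter119 limma called 0 miRNAs between the strains with all arrays, with 1 miRNA in each at an unadjusted p under 0.05. Leaving out B6 Prog replicate 2, 4 were called in Gr1 and 6 in Ter119, and these were named after their values were seen. Leaving out 1 further array gave 4 to 6 in Gr1 and 0 to 7 in Ter119, with 0 in Ter119 without B6 Ter119 replicate 1. miR-146b was higher in D2 Gr1, at 0.91 ± 0.41 (1.99 ± 0.18 without), in 2 of 2 D2 arrays. miR-139-5p, miR-342-3p and miR-150 were lower in D2 in both cell types, at -0.94 ± 0.47 (-1.01 ± 0.19 without), -0.21 ± 0.76 (-0.96 ± 0.19 without) and -0.07 ± 0.40 (-0.90 ± 0.18 without) in Gr1, where 1 of 2 D2 arrays was well above background for each of the last 2. In Ter119 they were -0.66 ± 0.42 (-0.73 ± 0.17 without), -0.57 ± 0.68 (-0.69 ± 0.17 without) and -0.55 ± 0.36 (-0.67 ± 0.16 without). In Ter119 miR-146a was also lower, at -0.33 ± 0.27 (-0.45 ± 0.12 without), and miR-188-5p and miR-370 were higher, at 1.06 ± 0.63 (0.92 ± 0.20 without) and 0.71 ± 0.31 (0.58 ± 0.14 without). With normexp and without that array 0 were called in either cell type.

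Averaged over the 4 cell types, 3 miRNAs were higher in D2: miR-146b by 0.97 ± 0.19 (1.17 ± 0.09 without), miR-652 by 0.74 ± 0.20 (0.25 ± 0.07 without) and miR-148a by 0.72 ± 0.19 (0.29 ± 0.10 without), with 11 D2 and 11 B6 arrays. Here the median of all tested miRNAs was 0.21 (0.04 without). miR-148a did not pass without B6 Prog replicate 2, where 19 were called, 14 higher and 5 lower in D2. With slide as a block 1 was called with all arrays and 20 without that array. Scaling on all probes gave 3 higher and 3 lower, quantile normalization 5 and 3, and no scaling 1 and 1. The strain by cell type interaction called 0 miRNAs by limma with all arrays, with 10 at an unadjusted p under 0.05, and 10 without B6 Prog replicate 2 (13 with slide as a block too).

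Further lists were called without B6 Prog replicate 2 alone. The miR-99 and miR-125 families share miR-99a and miR-125b-5p with the stem and progenitor list, and miR-125a-5p with the miR-99b cluster. Calls of these lists therefore rest partly on the same miRNAs and are not independent of each other. The miR-99 and miR-125 families were lower in Prog than in LSK (3 of 3 members, 3 adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.299 with an estimated correlation). They were higher in D2 LSK (3 of 3, 3 adjusted over the list alone, adjusted p = 0.00429, and adjusted p = 0.111 with an estimated correlation), in D2 Prog (2 of 3, 2 adjusted over the list alone, adjusted p = 0.00289, and adjusted p = 0.0951 with an estimated correlation) and in D2 on average (3 of 3, 3 adjusted over the list alone, adjusted p = 0.0081, and adjusted p = 0.13 with an estimated correlation). The miR-99b cluster was higher in D2 LSK (2 of 3, 2 adjusted over the list alone, adjusted p = 0.0461, and adjusted p = 0.299 with an estimated correlation). The lymphoid list was lower in D2 Gr1 (2 of 5, 2 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.359 with an estimated correlation), with a median of 0 and a mean of -0.35. The stem and progenitor list was higher in D2 on average (10 of 12, 10 adjusted over the list alone, adjusted p = 3.51e-08, and adjusted p = 0.0196 with an estimated correlation). As 8 of these 12, and 3 of 3 of the miR-99 and miR-125 families, were on no Gr1 or Ter119 array well above background, their averages rest on LSK and Prog.

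None of the 18 non-haematopoietic list members on the array was tested, and 2 of them, miR-10b and miR-203, were well above background on some array. Of the X-linked miR-322 cluster and the Dlk1-Dio3 imprinted cluster 2 members each were tested, and of the Sfmbt2 intronic cluster 0, too few for the list test. For families with near-identical members, such as let-7, miR-17 with miR-20 and miR-106, and miR-125a with miR-125b, 1 probe can bind several members, so single members are uncertain.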

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

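The splits of the arrays and the test of how far D2 LSK lies from Prog were set before their results were seen, and the tests of scaling, slide and other cells in the gate were chosen after the result was seen.

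Without B6 Prog replicate 2, 10 miRNAs differed in their strain effect between cell types by the interaction test, against 0 by limma with all 22 arrays. Their adjusted p-values were 6.19e-05 for miR-130a, 0.000137 for miR-146b, 0.000382 for miR-125b-5p, 0.00105 for miR-125a-5p, 0.00105 for let-7e, 0.00106 for miR-542-5p, 0.00180 for miR-196b, 0.00280 for miR-99a, 0.0069 for miR-222, and 0.0257 for miR-139-5p. For 8 of them, all but miR-146b and miR-139-5p, no Gr1 or Ter119 array was well above background, so the strain effect there is set by the floor and its difference from LSK and Prog is not measured. miR-139-5p was on no Prog array well above background, so its strain effect in Prog is set by the floor as well. Probes for miRNAs of a mouse herpesvirus, outside the comparisons, were well above background on 6 of 21 arrays for mghv-miR-M1-2 and on 11 for mghv-miR-M1-7-5p, while 8 of the 10 viral miRNAs were on none. The group means of these 2 lay between -4.38 and -3.64, near the floor of -4.38. Whether the virus was present was not tested.

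With all 22 arrays, 91.4% of the calls between Gr1 and Prog and 94.6% of those between Gr1 and Ter119 were lower in Gr1. With B6 Prog replicate 2 left out these shares were 51.4% and 50%, as scaling on the few probes that this array leaves would give. Whether Gr1 cells hold less of most miRNAs was not tested, and scaling removes a change common to all.

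For the 45 calls between Prog and LSK found with and without B6 Prog replicate 2, the change with slide as a block was 0.943 times the change without it (0.931 to 0.966 leaving out 1 Gr1 array), 45 had the same sign and 34 were called. Slide is separated here through the Gr1 arrays alone, and for a miRNA at the floor in Gr1 the block cannot show a slide difference. Of the 12 tested stem and progenitor members, 8 were on no Gr1 or Ter119 array well above background. The slope includes such miRNAs, so it does not decide whether slide is a cause. Scaling stays open and cannot be told apart from a change in cells for part of the 45 calls: 57.8%, or 26, had the same direction under all 4 scalings, 17 of the 36 lower and 9 of the 9 higher in Prog. Of the 11 stem and progenitor members among them 10 were lower under all 4.

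The stem and progenitor list was higher in D2 LSK without B6 Prog replicate 2, with medians of 0.43 to 0.65 under the 4 scalings. A shift of whole arrays moves miRNAs above the floor alike but not those at the floor, so it can move the list against the latter. Quantile normalization can also move a list against the others, and with it the list median was 0.51 (list test adjusted p = 4.16e-05). The list stayed higher under each of the 4 scalings, which argues against the choice among them as the cause. As each used a floor, a shift against miRNAs at the floor is not excluded. Gr1 or Ter119 cells in the B6 gate, in the share that gives the list median, are argued against: 3 members each lay over 3 SE below the predicted change, and miR-223 differed by -0.58 ± 0.23 where -4.35 is predicted for Gr1, and miR-451 by 0 ± 0.16 where -4.11 is predicted for Ter119. For members at the floor in Gr1 and Ter119 the SE can be too small, so the member counts weigh less than miR-223 and miR-451. For the list's own level scaling cannot be told apart from a change in cells: per array it was higher in D2 by 0.53 ± 0.18, but with scaling on all probes by 0.48 ± 0.45, or 1.07 SE. Prog cells in the B6 gate, at a share of 0.45, cannot be told apart either, with 2 such members. For them miR-223 differed by -0.58 ± 0.23 where -1.37 is predicted. Of the 6 miRNAs over 1 log2 higher in D2 Prog than in D2 LSK, 0 lay over 3 SE above the prediction, with an SE that counts error in the prediction too. Cells of other types and a difference between the strains' cells stay open as untested.

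Other splits of the same arrays show where a count that large comes by chance. With all 22 arrays, 1 of 100 splits gave as many calls for Prog against LSK (50, highest other 39), Gr1 against Prog (58, highest other 32), Ter119 against Prog (54, highest other 31), Gr1 against Ter119 (56, highest other 37) and the averaged strain comparison (3, highest other 0). That split was the real one, so chance is unlikely there, though the splits run cannot exclude it. For the interaction 100 of 100 splits gave as many as 0 (highest other 3), which any split reaches, so they decide nothing. With B6 Prog replicate 2 left out, 1 of 80 splits gave as many for Prog against LSK (65, highest other 45), 1 of 40 for Gr1 against Prog (70, highest other 23), 1 of 80 for Ter119 against Prog (72, highest other 62), 1 of 100 for Gr1 against Ter119 (60, highest other 55) and 1 of 100 for the averaged strain comparison (19, highest other 15). Chance is unlikely there too but not excluded, and some other splits came near the real count. For the interaction 4 of 100 gave as many as 10, and the highest other gave 21, so a count this large also arises with other splits. Within LSK and within Ter119 the 10 splits are too few for a share under 0.05. In LSK, with all arrays, 2 of 10 splits gave as many as the 5 calls, and the highest other gave 43, a structure that goes with the fit holding B6 Prog replicate 2: with that array left out, 1 of 10 gave as many as 19, and the highest other gave 0. In Ter119 10 of 10 gave as many as 0 (highest other 0), which any split reaches, and 1 of 10 as many as 6 without that array, with the highest other at 3. In Prog and Gr1 a group has under 3 arrays, so splits were not run.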

How the results depend on the processing

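Alternatives that leave out B6 Prog replicate 2 for results without Prog arrays, that join this with another choice, that block by scan session, that leave out slide A, or that use the slide block in the list test were chosen after seeing the data. Those that join 2 choices are given in this section as counts only. Their log2 changes were computed too, and some had the opposite sign to the fit without B6 Prog replicate 2. An example is miR-15a in Prog minus LSK, at 0.089 with scaling on all probes. Where no cause is named, the cause was not tested.

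Over the alternatives other than a left-out array alone, those that join leaving out B6 Prog replicate 2 with another choice included, the calls ranged from 0 to 69 for Prog minus LSK, from 4 to 85 for Gr1 minus Prog, from 3 to 82 for Ter119 minus Prog, from 5 to 72 for Gr1 minus Ter119, from 0 to 62 for strain in LSK, from 0 to 392 for strain in Prog, from 0 to 7 for strain in Gr1, from 0 to 7 for strain in Ter119, from 0 to 20 for the averaged strain comparison and from 0 to 40 for the interaction. A strict filter leaves fewer miRNAs to test. With no filter on dim probes, which gave the 392, all 567 mouse miRNAs are tested instead of 99. A shift of the median of all tested miRNAs against the fit with all arrays came with the scaling: 0.96 log2 for Gr1 minus Prog, 0.20 for Ter119 minus Prog, 0.79 for Gr1 minus Ter119, -0.45 for strain in LSK and 1.07 for strain in Prog with scaling on all probes, and 1.13, 0.30, 0.79, -0.45 and 0.78 with quantile normalization. With no scaling it was 0.48 for Prog minus LSK, 0.61 for Gr1 minus Prog, 0.77 for Gr1 minus Ter119, -0.37 for strain in LSK and 0.29 for strain in Prog, and -0.17 for the averaged strain comparison. For strain in Ter119 the shifts were -0.33, -0.13 and -0.18 with these 3 scalings. Array weights ran from 0.0342 to 4.33, and their fit stopped before convergence. Signal over background limits the dim miRNAs, whose values at the floor have no spread.

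Calls that moved by over 1.5 times are these. Scaling on all probes gave 24 for Prog minus LSK, 31 for Gr1 minus Ter119, 1 for strain in LSK, 56 for strain in Prog, 2 for strain in Gr1, 3 for strain in Ter119, 6 for the averaged strain comparison, 3 for the interaction and 13 for miRNA lists. Quantile normalization gave 37 for Gr1 minus Ter119, 3 for strain in LSK, 46 for strain in Prog, 3 for strain in Gr1, 2 for strain in Ter119, 8 for the averaged strain comparison, 7 for the interaction and 13 for miRNA lists. No scaling gave 32 for Prog minus LSK, 30 for Gr1 minus Ter119, 3 for strain in LSK and 0 for strain in Prog. Normexp background gave 12 for Prog minus LSK, 21 for Ter119 minus Prog, 0 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. Floor 2 times higher gave 34 for Gr1 minus Prog, 30 for Ter119 minus Prog, 10 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. No floor gave 0 for strain in LSK, 28 for strain in Prog and 1 for strain in Gr1. Mean of probes gave 10 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. Total gene signal gave 2 for strain in LSK, 39 for strain in Prog and 1 for strain in Gr1. No filter on dim probes gave 2 for strain in LSK, 392 for strain in Prog and 0 for the averaged strain comparison. Strict filter on dim probes gave 1 for Prog minus LSK, 4 for Gr1 minus Prog, 3 for Ter119 minus Prog, 5 for Gr1 minus Ter119, 0 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. Log2 change of at least 1 gave 31 for Prog minus LSK, 33 for Ter119 minus Prog and 0 for the averaged strain comparison. A fit by eBayes with trend and robust gave 23 for strain in Prog and 1 for the averaged strain comparison. Array weights gave 21 for Prog minus LSK, 28 for Gr1 minus Prog, 20 for Ter119 minus Prog, 62 for strain in LSK, 0 for strain in Prog, 5 for strain in Gr1, 6 for strain in Ter119, 1 for the averaged strain comparison and 40 for the interaction. Only the compared groups gave 0 for strain in LSK, 0 for strain in Prog and 1 for strain in Gr1. Slide as fixed block gave 0 for Prog minus LSK, 37 for Gr1 minus Prog, 2 for strain in LSK, 0 for strain in Prog and 1 for the averaged strain comparison. Slide as random block gave 3 for strain in LSK and 6 for the averaged strain comparison. The authors' value table gave 82 for Ter119 minus Prog, 2 for strain in LSK, 3 for strain in Prog, 7 for strain in Gr1 and 15 for the averaged strain comparison. The authors' processed Cy3 table gave 42 for strain in Prog, 1 for strain in Gr1 and 12 for the averaged strain comparison. Scan session block gave 0 for Prog minus LSK, 37 for Gr1 minus Prog, 1 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. Leaving out slide A gave 0 for strain in Prog. Slide block and no B6 Prog array 2 gave 22 for strain in LSK, 6 for strain in Prog, 5 for strain in Gr1, 7 for strain in Ter119, 20 for the averaged strain comparison and 13 for the interaction. All-probe scaling and no B6 Prog array 2 gave 32 for Prog minus LSK, 35 for Gr1 minus Ter119, 1 for strain in LSK, 3 for strain in Prog, 2 for strain in Gr1, 3 for strain in Ter119 and 6 for the averaged strain comparison. Quantile normalization and no B6 Prog array 2 gave 24 for strain in LSK, 4 for strain in Prog, 4 for strain in Gr1, 3 for strain in Ter119, 10 for the averaged strain comparison and 10 for the interaction. No scaling and no B6 Prog array 2 gave 0 for strain in Prog, 3 for strain in Gr1 and 6 for the averaged strain comparison. Normexp and no B6 Prog array 2 gave 32 for Prog minus LSK, 26 for Gr1 minus Prog, 26 for Ter119 minus Prog, 34 for Gr1 minus Ter119, 0 for strain in LSK, 0 for strain in Prog and 0 for the averaged strain comparison. No floor and no B6 Prog array 2 gave 2 for strain in LSK, 2 for strain in Prog, 3 for strain in Gr1 and 1 for strain in Ter119. Fry gave 25 for miRNA lists. Estimated correlation gave 0 for miRNA lists.

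Replicate numbers showed no pairing of the arrays on average, and with the replicate block the calls were 48 for Prog minus LSK, 52 for Gr1 minus Prog, 49 for Ter119 minus Prog, 55 for Gr1 minus Ter119, 2 for strain in LSK and 1 for the averaged strain comparison. The correlation within slide as a random block was -0.120.

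Log2 changes of the opposite sign to the fit with all arrays are these. Scaling on all probes gave miR-125a-5p -0.34 for Prog minus LSK. Scaling on all probes gave let-7i 0.016, miR-10a 1.23, miR-146b 0.62, miR-142-3p 1.56, miR-27a 1.01, miR-150 0.55, miR-342-3p 0.75, let-7c 0.060, let-7d 0.093, miR-15b 1.99 and miR-322 0.27 for Gr1 minus Prog. Scaling on all probes gave miR-15a 0.54, miR-142-3p 0.63, miR-21 0.27, miR-29b 0.17 and miR-15b 0.31 for Gr1 minus Ter119. Scaling on all probes gave miR-188-5p 0.027, miR-34a 0.17, miR-196b 1.46, miR-10a 1.31, miR-486 0.77, miR-125b-5p 2.03, miR-27b 0.91 and miR-494 2.20 for strain in Prog. Quantile normalization gave miR-125a-5p -0.47 for Prog minus LSK. Quantile normalization gave let-7i 0.33, miR-10a 1.37, miR-146b 0.85, miR-142-3p 1.84, miR-21 0.11, miR-27a 1.17, miR-150 0.72, miR-342-3p 0.68, let-7c 0.26, let-7d 0.42, miR-15b 1.33 and miR-322 0.41 for Gr1 minus Prog. Quantile normalization gave let-7b 0.029 for Ter119 minus Prog. Quantile normalization gave miR-221 0.58, miR-15a 0.73, miR-142-3p 0.82, miR-21 0.45, miR-181a 0.13, miR-23b 0.99 and miR-29b 0.24 for Gr1 minus Ter119. Quantile normalization gave miR-196b 1.12, miR-10a 1.09, miR-125b-5p 1.83, miR-494 1.43 and the stem and progenitor list 0.79 for strain in Prog. No scaling gave miR-221 0.032, miR-106b 0.16 and miR-17* 0.11 for Prog minus LSK. No scaling gave miR-27a 0.15 and miR-15b 0.89 for Gr1 minus Prog. No scaling gave miR-15a 0.39, miR-142-3p 0.47, miR-21 0.11, miR-29b 0.013 and miR-15b 0.15 for Gr1 minus Ter119. Normexp background gave miR-671-5p -0.068, miR-139-5p -0.28, miR-22 -0.40 and miR-24 -0.73 for Gr1 minus Prog. Normexp background gave miR-125a-3p -0.18 for Ter119 minus Prog. Normexp background gave miR-10a -0.098 for Gr1 minus Ter119. No floor gave miR-18a -0.95 and miR-19a -0.28 for Prog minus LSK. No floor gave miR-21 0.53 for Gr1 minus Prog. No floor gave miR-29c 3.56 for strain in Prog. Total gene signal gave miR-146b 1.54, miR-142-3p 1.11, miR-21 0.80, miR-27a 0.54, miR-181a 0.30, miR-23b 0.36, miR-29b 1.37, miR-15b 1.27 and miR-322 0.64 for Gr1 minus Prog. Total gene signal gave miR-221 1.75, miR-15a 0.87, miR-142-3p 0.96, miR-21 0.71, miR-181a 0.35, miR-106b 0.011, miR-23b 1.16, miR-29a 0.084, miR-29b 0.50, miR-29c 0.80 and miR-15b 0.59 for Gr1 minus Ter119. The authors' value table gave miR-26a 0.049, miR-125a-5p -3.48, miR-221 0.14, miR-15a 0.31, miR-16 0.92, miR-21 0.14, miR-23a 0.18, miR-181a 0.10, miR-106b 0.89, miR-17* 0.39, let-7a 0.11, let-7f 0.44, miR-23b 0.38 and miR-29a 0.11 for Prog minus LSK. The authors' value table gave miR-146b 0.59, miR-27a 0.65, miR-150 1.07, miR-342-3p 2.07 and miR-125a-3p 0.89 for Gr1 minus Prog. The authors' value table gave miR-23a -0.93, miR-25 -0.42, let-7g -0.77 and miR-29a -0.51 for Ter119 minus Prog. The authors' value table gave miR-125b-5p 0.78, miR-221 1.505, miR-15a 0.36, miR-142-3p 0.58, miR-21 0.28, miR-181a 0.042, miR-23b 0.93, miR-29b 0.12 and miR-15b 0.0050 for Gr1 minus Ter119. The authors' value table gave miR-16 -0.13, miR-25 -0.012, miR-93 -0.012, miR-125a-5p 2.36, miR-188-5p 0.19 and let-7e 2.08 for strain in Prog. The authors' value table gave miR-125a-5p 0.89 and miR-486 -0.52 for the averaged strain comparison. For the miR-23, miR-27 and miR-24 list in Gr1 minus Prog the direction of the test alone differed. Its mean was -0.70 in both tests, and fry gave it as lower (adjusted p = 0.0374), while camera gave it as higher relative to the other miRNAs.

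Leaving out each array in turn gave calls of 43 to 101 for Prog minus LSK, 1 to 41 for strain in LSK, 1 to 75 for the averaged strain comparison, 0 to 81 for the interaction, 44 to 109 for Gr1 minus Prog, 46 to 100 for Ter119 minus Prog, 0 to 89 for strain in Prog, 0 to 4 for strain in Gr1 and 0 to 6 for strain in Ter119. The highest counts for the comparisons of Prog, for the averaged strain comparison and for the interaction come without B6 Prog replicate 1, which leaves the doubted array alone in its group, for strain in LSK without D2 LSK replicate 2, and for strain in Gr1 and Ter119 without B6 Prog replicate 2. In Prog minus LSK the log2 changes ranged over miR-125a-5p -0.63 to 1.44, miR-16 -2.43 to 0.043, miR-150 -0.29 to 0.43, miR-181b -0.75 to 1.55, miR-181d -0.75 to 1.66 and miR-106b -1.65 to 0.15. In Gr1 minus Prog the log2 changes ranged over miR-10a -1.26 to 1.39, miR-146b -0.36 to 0.95, miR-142-3p -0.79 to 1.11, miR-27a -1.61 to 1.04, miR-150 -0.94 to 0.70, miR-342-3p -2.35 to 1.04, miR-15b -0.27 to 1.19 and miR-322 -1.17 to 0.29. In Ter119 minus Prog the log2 changes ranged over miR-21 -0.98 to 0.81, miR-24 -0.65 to 0.47 and miR-342-3p -0.35 to 2.02. In Gr1 minus Ter119 the log2 changes ranged over miR-221 -0.021 to 0.53, miR-15a -1.002 to 0.61, miR-16 -0.88 to 0.63, miR-142-3p -0.89 to 0.69, miR-21 -1.21 to 0.33, miR-181a -0.71 to 0.085, miR-23b -0.58 to 0.96, miR-29b -1.31 to 0.23, miR-29c -0.49 to 0.50 and miR-15b -1.15 to 0.37. In strain in LSK the log2 changes ranged over miR-16 -0.26 to 0.70 and miR-181b -0.41 to 0.39. In strain in Prog the log2 changes ranged over miR-16 -0.11 to 4.54, miR-15a -0.15 to 2.81, miR-149 -4.90 to 0.0030, miR-196b -2.42 to 0.74 and miR-125b-5p -1.72 to 1.35. In the averaged strain comparison the log2 changes ranged over miR-125a-5p -0.89 to 0.15 and miR-16 -0.13 to 1.21. Without B6 Prog replicate 2 there were a mean of 0.52 for the stem and progenitor list in strain in Prog, a mean of 0.71 for the miR-99 and miR-125 families list in strain in Prog, a mean of -0.031 for the miR-17 family clusters list in strain in Prog and 18 calls of the list test.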

Other observations

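The test of how far D2 LSK lies from Prog was set before its result was seen, and the miRNAs in the next paragraph were chosen after their values were seen.

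Without B6 Prog replicate 2, the level of miR-223 (log2 scaled signal ± SD) was 4.95 ± 0.05 in B6 Gr1 and 4.97 ± 0.10 in D2 Gr1, and miR-92a, of the miR-17 family clusters, was 2.29 ± 0.14 in B6 LSK and 1.95 ± 0.16 in D2 LSK. miR-125a-3p was well above background on 6 of 6 Ter119 arrays and on no Prog array, at least 1.42-fold higher in Ter119 (2.29-fold without B6 Prog replicate 2), while miR-125a-5p, from the same precursor, and let-7e, from the same cluster, were on no Ter119 array well above background. miR-322, of an X-linked cluster, was lower in Prog than in LSK, at -1.18 ± 0.25 (-0.91 ± 0.13 without), and lower in Ter119 than in Prog, at -1.31 ± 0.25 (-1.38 ± 0.13 without).

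A hypothesis is that D2 LSK cells may lie further from Prog cells than B6 LSK cells do. Across 39 miRNAs outside the stem and progenitor list and the miR-17 family clusters, without B6 Prog replicate 2, the strain difference in LSK and the difference of Prog from LSK had r = -0.567 (Spearman -0.514), and miRNAs are not independent replicates. In 1000 simulated sets of arrays with no strain difference the 2.5th percentile was -0.448 and its upper counterpart 0.440. The value lay beyond these and was -0.566 with scaling on all probes and -0.607 with quantile normalization. Of the 10 splits of the LSK arrays 1, the real one, gave a value as far from 0, but the highest other lay at 0.5002 from 0, beyond the simulated limits too, and 10 splits are too few for a share under 0.05. The hypothesis cannot be told apart from chance or from Prog cells in the B6 LSK gate.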
